A study of Homo sapiens with 6 samples.

How the data were processed

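Polyadenylated RNA of 6 samples of the PC9 line was sequenced, 3 untreated parental and 3 resistant and kept in 100 nM dacomitinib. Per the labels' protocols, libraries were made with a modified bulk form of MARS-seq, in which barcoded primers start reverse transcription at the poly(A) tail, samples are pooled and RNA is amplified by in vitro transcription. Reads of such libraries come from 3′ ends, so a count does not depend on transcript length, and a gene with an unusual 3′ end can be missed. RPL10, RPL13 and NDUFA4, which nearly all cells use, had mean normalized counts of 0.571, 1.92 and 0.157 in the authors' deposited table, so a count near 0 is not read as absence. Per the submitters' processing notes, cutadapt, STAR, HTSeq and DESeq2 were used with the GRCh38 (hg38) build, in versions and with settings not given in the sources used here. Whether molecular barcodes were collapsed and whether counting used strand are also not given in the sources used here, so antisense, overlapping and near-identical genes are uncertain.

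The data analysed here are the authors' deposited table of their own comparison, with 1 row per gene. Per the file headers, it holds a mean normalized count, a signal averaged over all libraries of the authors' fit. It also holds, per the file headers, a log2 fold change and its standard error. The Wald statistic is a score in the authors' deposited table that equals the fold change divided by its standard error. The authors' deposited table gives a p-value for each gene with reads and a Benjamini-Hochberg adjusted p-value for 13494 genes. Recomputing the adjustment over these genes gave the deposited values with a largest difference of 1.6e-15. The authors' deposited table has 10618 genes at a mean count of 0 and 2373 with reads but no adjusted p, the highest of them at 0.759. The headers do not state the direction of the fold change. It is read as resistant over parental because the design sets resistant against parental cells, and every direction given rests on this reading.

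The plan made before the data were examined was a count test across the 6 samples, and a description of the authors' results where only their comparison was at hand. The second case applied: calls are those of the authors' Wald test, per the submitters' processing notes made with DESeq2, at an adjusted p under 0.05 and two-sided. Labels number the replicates but do not say that they came from separate cultures, so the p-values measure the spread between these samples, which may be technical.

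Depth was read from the lowest mean counts. A gene with 1 read in 1 library has a mean set by that library's size factor, and 6 such values recurred, 3 with folds above and 3 with folds below 0. All 2685 genes with a mean above 0 and below 1 were whole-read combinations of these within a tolerance of 6e-07, against 0.0876% expected by chance. The 6 values were taken from these same genes, so the genes at the values themselves fit by construction. The implied size factors were 0.539, 1.03 and 1.08 on the side read as parental and 1.06, 1.19 and 1.37 on the side read as resistant. They were not tied to replicate numbers. The 10 most abundant genes held 6.98% of the summed mean counts. No intervals for counting error were computed, and fold intervals are 95% normal intervals from the authors' standard errors.

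Gene lists, 34 in number, were fixed before the data were examined, and 33 with at least 5 tested members were tested. The mitochondrial transcripts list matched 0 names and was not analysed here. The planned test, limma's camera, needs values per library, so its preranked form (cameraPR, limma 3.58.1 in R 4.3.3) was run on the authors' Wald statistic with a preset inter-gene correlation of 0.01, two-sided, with Benjamini-Hochberg adjustment over the 33 lists. An estimated correlation and fry need values per library and were not run, so preset correlations of 0.05 and 0.1 stand in their place. Counts adjusted over the list alone equalled those over all genes wherever no second pair is given. Where a member's lower group had a fitted mean count under 1, which is 3 reads over 3 libraries, its fitted fold depends on the fit, so no fold is printed for such genes and list medians were also taken with that group set to 1. Group means were derived from the mean count and the fold.

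Named genes follow a rule fixed before the data were examined. The rule takes the 10 largest rises and 10 largest falls among called genes with a mean CPM of at least 20 (a mean normalized count of 79.3), up to 3 rises and 3 falls per list, and 9 genes set in advance (EGFR, AXL, VIM, CDH1, ZEB1, ALDH1A1, ALDH1A3, DUSP6 and MKI67). Its further condition, that libraries of the groups not overlap, could not be applied. HLA-C, NLRC5 and ACTA2 were added after their values were seen. Some genes that the rule takes are not reported here. Positions came from GENCODE 29 by symbol, for 12639 tested genes (93.7%).

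For position effects, the median fold was taken over each 30 neighbouring genes among 6684 with a mean count of at least 50, and compared with 1000 shuffled gene orders. The standard error of the median fold of the neighbours of EGFR came from 10000 bootstrap draws of these genes. Ribosomal protein genes inside and outside lowered stretches were also compared, by medians and afterwards by means, with exact permutation tests. These p-values are not used, because the stretches had been drawn from the folds of the same genes.

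The calling of genes was tested on simulated data with the standard errors of the real table and 200 changed genes among 13494. These are fewer than the 3800 genes called in the real table, and the adjustment is stricter where fewer genes change. The shares called are therefore not the sensitivity of the real table. Of genes changed 1.5-fold, 20.9% of 67 were called, against 59.7% of 67 at 2-fold and 74.2% of 66 at 4-fold, and 8 unchanged genes (7.21% of calls) were called. The list test was instead run on the real Wald statistics shuffled over genes, with those of the hypoxia list raised by a fixed amount. It called the 1 shifted list and 1 of 32 other lists, some of which share genes with the hypoxia list. Shuffling removes correlation between genes, so this run cannot check the preset correlation. Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 were used. Alternatives were other thresholds, filters, centrings, list tests and the removal of shifted stretches.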

Results

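Gene expression was measured by RNA sequencing of polyadenylated RNA in PC9 cells, a human lung adenocarcinoma line whose growth is driven by a mutant, active EGFR. Resistant cells had been derived from the parental line with dacomitinib, a covalent inhibitor of the EGFR-family kinases, whose dose was raised from 1 pM to 100 nM over 6 months. The design compared 3 libraries of resistant cells kept in 100 nM dacomitinib with 3 libraries of untreated parental cells, so the resistant state and the presence of drug were not separated. The authors' deposited table listed 26485 genes, of which 15867 had reads and 13494 had an adjusted p-value. In the authors' deposited table the mean normalized counts of all genes summed to 3.97e+06 per library, and the size factors that the low values imply ran from 0.539 to 1.37. The median standard error in the authors' deposited table was 0.15 log2 units for genes with a mean normalized count of 50 or more and 0.62 below that count. Values per library were not analysed here, and all folds are log2 ratios of resistant to parental cells with their standard error (SE), where a positive value is read as higher in resistant cells. Gene positions are those of GRCh38.

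The comparison of resistant with parental cells asked which transcripts accompany acquired resistance to the inhibitor. Resistant cells had more transcript of genes of mesenchymal cells, of antigen presentation and of TGF-beta signalling, and less of the lists of mucins and secretory genes and of MAPK output. An adjusted p of 0.05 was passed by 3800 genes of the authors' deposited table, 28.2% of those tested, with 1801 higher and 1999 lower in resistant cells. Of these, 1382 differed by at least 2-fold in the authors' deposited table, 731 of them higher and 651 lower. The median log2 fold change of the 6952 genes with a mean normalized count of 50 or more was -0.03 in the authors' deposited table, and centring on it gave 1935 higher and 1859 lower.

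The largest rise among well-expressed genes was that of PDGFRB, the beta receptor for platelet-derived growth factor, at 8.17 ± 0.60 (adjusted p = 1.15e-40) in the authors' deposited table. It lies on chromosome 5, from 150113837 to 150155872, and its fitted mean count was 2.27 in parental and 651 in resistant cells by the authors' deposited table. Next in the authors' deposited table came the cytokine IL32 at 7.19 ± 0.60 and the heparin-binding growth factor PTN at 5.96 ± 0.57. HLA-B, a class I antigen-presenting molecule, stood at 5.62 ± 0.36 in the authors' deposited table, with adjusted p = 8.4e-52. TAGLN, an actin-binding protein of contractile cells, rose by 5.45 ± 0.29, and the matrix protein FN1 by 5.40 ± 0.12, with an adjusted p listed as 0 for FN1, in the authors' deposited table. The adhesion molecule MCAM (4.55 ± 0.16), the collagen gene COL16A1 (4.47 ± 0.37), the alpha-tubulin gene TUBA1A (4.15 ± 0.33) and the cytokine IL11 (4.01 ± 0.33) completed the 10 largest rises in the authors' deposited table. MCAM and TAGLN lie in a stretch of chromosome 11 with 61 of 71 genes below 0 and a median fold change of -0.59. PDGFRB lies in a stretch of chromosome 5 with 28 of 47 genes below 0, whose median was only -0.09.

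The largest fall among well-expressed genes was that of CASP14, a protease of terminally differentiating keratinocytes, at -8.27 ± 0.60 (adjusted p = 3.87e-41) in the authors' deposited table. The 10 largest falls among these genes also held the keratin genes KRT13, KRT5 and KRT6B, KRT13 standing at -7.37 ± 0.19 with an adjusted p listed as 0, KRT5 at -6.03 ± 0.36 and KRT6B at -5.27 ± 0.35, in the authors' deposited table. The peroxisomal oxidase ACOX2 (-6.64 ± 0.57), the trefoil peptide TFF2 (-6.62 ± 0.61), RARRES1 (-6.40 ± 0.31), the surface protein LY6D (-5.40 ± 0.26), the IGF-binding protein IGFBP2 (-4.19 ± 0.13) and the pseudokinase TRIB2 (-4.03 ± 0.31) were the other genes among the 10 largest falls in the authors' deposited table. TRIB2 lies in a stretch of chromosome 2 whose median fold change was -0.84.

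**Figure D1:**
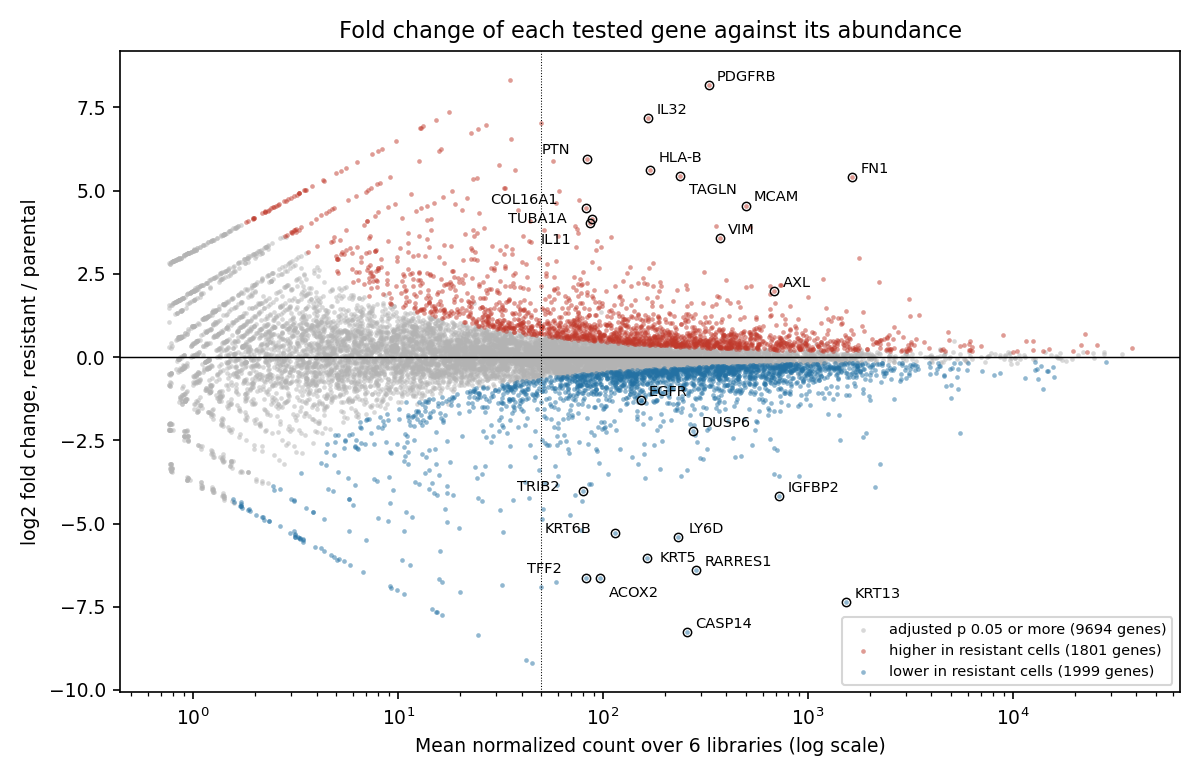
Each point is 1 of the 13494 tested genes, with its mean normalized count over the 6 libraries on a log axis and its log2 fold change (resistant over parental) on the other, and the dotted line marks a mean count of 50. The 1801 genes called higher and 1999 called lower are coloured, and named genes such as PDGFRB (8.17) and CASP14 (-8.27) are circled.

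EGFR itself, the target of the drug, was lower in resistant cells, with a log2 fold change of -1.28 ± 0.16 and adjusted p = 2.19e-14 in the authors' deposited table. It lies at chromosome 7, from 55019021 to 55211628. DUSP6, a phosphatase that ERK signalling induces, fell by 2.23 ± 0.13 (adjusted p = 2.15e-60) in the authors' deposited table. Of 26 tested genes of the MAPK output list, 17 were lower and 4 higher in the authors' deposited table, and the list as a whole was lower with an adjusted p of 8.9e-14 and a median of -0.84. Adjusted over the list alone, 18 were lower and 5 higher. The largest falls in the authors' deposited table were those of the transcription factor gene FOS (-4.23 ± 0.43) and the receptor kinase antagonists SPRY4 (-3.82 ± 0.28) and SPRY1 (-2.64 ± 0.28). SPRED3 (2.67 ± 0.79), SPRY2 (0.72 ± 0.27) and the urokinase receptor PLAUR (0.62 ± 0.11) rose in the authors' deposited table. The ERBB family list held receptors, their ligands and other genes such as ERRFI1, CBLC and SOCS4. Of its 16 tested genes, 7 were lower and 3 higher in the authors' deposited table, 8 and 4 when adjusted over the list alone. The list did not pass its test (adjusted p = 0.167). Its ligand genes EREG (-2.05 ± 0.31) and HBEGF (-1.05 ± 0.14) fell, while NRG1 (2.51 ± 0.64) rose, in the authors' deposited table. LRIG1, a negative regulator of ERBB receptors, was also called higher in the authors' deposited table, at a mean count of 12.8 with parental cells near 0.

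AXL, a receptor tyrosine kinase at chromosome 19, from 41219203 to 41261766, rose by 1.99 ± 0.09 (adjusted p = 7.14e-98) in the authors' deposited table, a 3.97-fold difference. Its ligand gene GAS6 rose by 3.94 ± 0.17 (adjusted p = 1.59e-120) in the authors' deposited table. Of 20 tested genes of receptor tyrosine kinases outside the ERBB family and their ligands and binding proteins, 5 were higher and 4 lower in the authors' deposited table, without a shift of the list (adjusted p = 0.174). ROR1 (-0.79 ± 0.21) and MST1R (-0.60 ± 0.16) were among the lower ones in the authors' deposited table.

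Mesenchymal genes rose as a group while epithelial genes did not move as one. The fibroblast markers PDGFRB, COL1A1 and C1S rose beside them, by 8.17, 4.11 and 2.67, while FBLN1 (-2.35) and SFRP1 (-0.76) of the same marker list fell, in the authors' deposited table. Of 23 tested mesenchymal genes, 12 were higher and 2 lower in the authors' deposited table, with a list median of 2.14 and an adjusted p of 2.21e-18. With the 5 members whose lower group had a fitted mean count under 1 set to that count, the median was 1.35. VIM, the intermediate filament protein of mesenchymal cells at chromosome 10, from 17228259 to 17237593, rose by 3.57 ± 0.15 (adjusted p = 1.71e-124) in the authors' deposited table. COL5A1, a fibrillar collagen gene, was called higher with it in the authors' deposited table, from a fitted parental count under 1 to 70.6. Against the direction of the list, the calcium-binding protein gene S100A4 fell by 3.63 ± 0.21 and COL6A1 by 0.59 ± 0.07 in the authors' deposited table. ACTA2, chosen after its values were seen, had a mean count of 1.99 and did not pass (adjusted p = 0.133) in the authors' deposited table. ZEB1, a repressor of epithelial genes, had a mean count of 0.523 and no adjusted p in the authors' deposited table.

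Of 35 tested epithelial genes, 10 were higher and 8 lower in the authors' deposited table, with a list median of -0.05 and an adjusted p of 0.776. CDH1, the adherens junction cadherin, had a log2 fold change of -0.18 ± 0.13 that did not pass (adjusted p = 0.353) in the authors' deposited table, with a 95% interval from -0.43 to 0.08. The tight junction gene CLDN1 (1.16 ± 0.17) and the simple-epithelium keratin KRT7 (0.68 ± 0.06) rose in the authors' deposited table. OVOL1 (-1.93 ± 0.19) and the membrane proteases ST14 (-1.13 ± 0.08) and PRSS8 (-0.91 ± 0.30) fell in the authors' deposited table, of which OVOL1 and ST14 lie in lowered stretches of chromosome 11.

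Mucins and secretory genes fell as a list, whereas the fall of the squamous list depended on the setting. Of 11 tested squamous or basal cell genes, 7 were lower and 3 higher in the authors' deposited table, 8 and 3 when adjusted over the list alone, with a list adjusted p of 0.00473. The median was -3.66, or -1.90 with 5 low members set to a count of 1, and the list did not pass at a preset correlation of 0.1 (adjusted p = 0.0699) or in rank form (adjusted p = 0.0752). KRT5 fell, and SPRR1B and SPRR3, which build the cornified envelope, were called lower from fitted parental counts of 32.7 and 31.2 to under 1 in the authors' deposited table. KRT17 and TP63, a regulator of basal cells, were called higher from under 1 to 99.3 and 26.2, and TRIM29 rose by 0.99 ± 0.07, in the authors' deposited table. Of 16 tested mucins and secretory genes, 10 were lower and 3 higher in the authors' deposited table, with a list adjusted p of 1.16e-15. The median of that list was -2.78, or -1.72 with 2 low members set to a count of 1. TFF2 and TFF1 (-3.81 ± 0.28) fell, and MUC5B was called lower from a fitted parental count of 49.1 to under 1, in the authors' deposited table. MUC4 (2.12 ± 0.16), MUC1 (1.27 ± 0.34) and the protease inhibitor SLPI (0.62 ± 0.06) rose in the authors' deposited table.

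**Figure D2:**
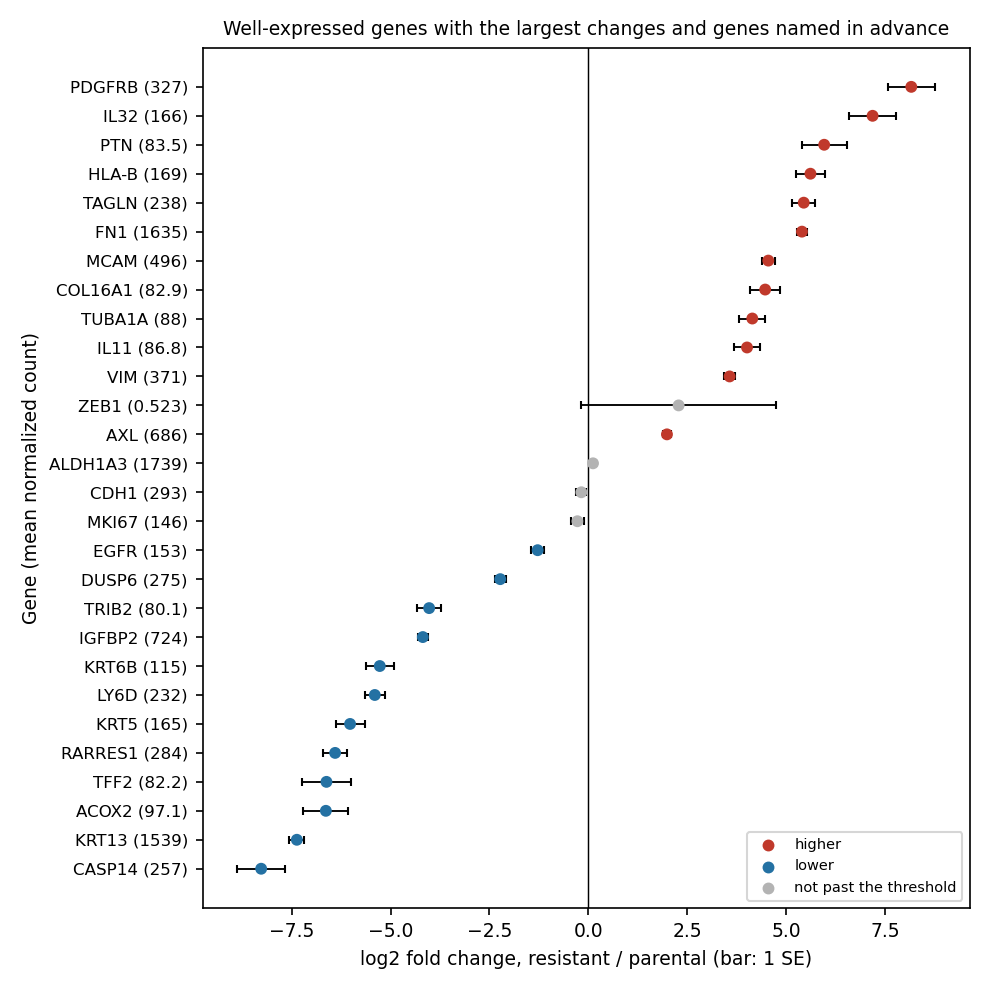
Points give the log2 fold change (resistant over parental) of the 20 genes with the largest changes among called genes with a mean CPM of at least 20 and of the genes named in advance that had a fold, with bars of 1 SE and the mean normalized count in parentheses. VIM (3.57) and AXL (1.99) lie above 0, EGFR (-1.28) and DUSP6 (-2.23) below it, and CDH1 (-0.18), ALDH1A3 (0.12), MKI67 (-0.28) and ZEB1 did not pass the threshold.

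Targets of TGF-beta and of YAP and TEAD were higher. Of 22 tested TGF-beta targets, 15 were higher and 2 lower in the authors' deposited table, with a median of 1.13 and a list adjusted p of 2.46e-09. The cyclin-dependent kinase inhibitor CDKN1A rose by 2.52 ± 0.20 and ID3 by 2.13 ± 0.10 in the authors' deposited table. ID1 fell by 2.47 ± 0.10, and LTBP3 by 0.79 ± 0.08, in the authors' deposited table. Of 22 tested YAP and TEAD targets, 10 were higher and 2 lower in the authors' deposited table, with a median of 0.67 and a list adjusted p of 1.85e-05. The kinase gene NUAK2 rose by 3.34 ± 0.48, while CTGF and ANKRD1 were called higher at mean counts of only 4.32 and 3.13, in the authors' deposited table. IGFBP3 (-0.51 ± 0.08) and MYOF (-0.36 ± 0.12) fell in the authors' deposited table.

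Antigen presentation genes rose, whereas interferon-response genes moved both ways. Of 17 tested antigen presentation genes, 12 were higher and 1 lower in the authors' deposited table, with a median of 1.45 and a list adjusted p of 1.63e-11. HLA-B led the rise, followed by the immunoproteasome subunit PSMB9 (4.48 ± 0.93) and HLA-F (2.93 ± 0.49), in the authors' deposited table. HLA-C (1.03 ± 0.08) and NLRC5 (2.74 ± 0.40), a transcriptional activator of class I genes, were chosen after their values were seen and also rose in the authors' deposited table. Class I genes are close in sequence, so their reads may be divided between them. The lower member was PSMB10 (-0.27 ± 0.10) in the authors' deposited table, whose call was lost after centring (adjusted p = 0.0639). Of 26 tested interferon-response genes, 3 were higher, 3 lower and 20 did not pass in the authors' deposited table (list adjusted p = 0.655). The median of that list was 0.43, so it lay on the same side of 0 as that of antigen presentation. IFIT3 (1.45 ± 0.53), DDX58 (1.05 ± 0.38) and IFITM3 (0.74 ± 0.21) rose, and OAS1 (-1.96 ± 0.55), IRF7 (-1.69 ± 0.52) and IFI35 (-1.09 ± 0.21) fell, in the authors' deposited table.

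Among 24 tested NF-kB targets and cytokines, 11 were higher and 4 lower in the authors' deposited table, with a median of 0.92. The list did not pass (adjusted p = 0.118) but did in rank form (adjusted p = 0.0310). IL32 and IL6 (5.39 ± 0.89) rose, and TRAF1 was called higher from a fitted parental count under 1 to 35.3, in the authors' deposited table. The siderophore-binding protein LCN2 (-2.98 ± 0.11), complement component C3 (-2.07 ± 0.37) and TNFAIP2 (-0.66 ± 0.07) fell in the authors' deposited table.

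Cell cycle genes were lower by small amounts. Of 36 tested cell cycle genes, 18 were lower and 0 higher in the authors' deposited table, with a median of -0.29 and a list adjusted p of 5.29e-05, which was 0.0691 at a preset correlation of 0.1. At an unadjusted p of 0.05 of the authors' Wald test, 18 were lower and 0 higher. CENPA (-1.23 ± 0.14), the ribonucleotide reductase subunit RRM2 (-1.21 ± 0.14) and the mitotic cyclin CCNB1 (-1.09 ± 0.08) fell most in the authors' deposited table, and CENPA and RRM2 lie in a lowered stretch of chromosome 2. MKI67, the proliferation marker, had a log2 fold change of -0.28 ± 0.16 that did not pass (adjusted p = 0.2) in the authors' deposited table.

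Of 28 tested NRF2 targets, 16 were lower and 4 higher in the authors' deposited table, with a median of -0.33 and a list adjusted p of 4.13e-06. The aldo-keto reductase AKR1B10 (-2.27 ± 0.06), the export pump ABCC2 (-2.09 ± 0.20) and the peroxidase GPX2 (-1.01 ± 0.08) fell, and TXN (0.50 ± 0.08), GCLM (0.38 ± 0.09) and the ferritin light chain FTL (0.36 ± 0.06) rose, in the authors' deposited table. Of 14 tested aldehyde dehydrogenase genes, 4 were higher and 4 lower in the authors' deposited table (list adjusted p = 0.174, with a median of 0.03 and a mean of -0.62). ALDH1A3 did not pass at 0.12 ± 0.08 (adjusted p = 0.273), and ALDH1A1 was listed at a mean count of 0, in the authors' deposited table. ALDH2 (1.23 ± 0.17), ALDH6A1 (1.07 ± 0.30) and ALDH3B1 (0.70 ± 0.13) rose and ALDH3A1 (-2.74 ± 0.11) and ALDH3B2 (-1.59 ± 0.32) fell in the authors' deposited table, where ALDH1L1 was called lower from a fitted parental count of 29.2. Of 11 tested drug efflux transporters, 2 were higher and 4 lower in the authors' deposited table (list adjusted p = 0.513, with a median of 0.03 and a mean of -0.38). ABCA1 (-4.00 ± 0.87) and ABCC3 (-0.72 ± 0.10) fell with ABCC2, and the vault protein MVP (0.87 ± 0.11) and ABCA2 (0.66 ± 0.20) rose, in the authors' deposited table.

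Glycolysis genes were lower, 9 of 20 tested with 1 higher in the authors' deposited table and 12 with 1 when adjusted over the list alone. Their median was -0.27 and the list adjusted p 0.00152, which was 0.0744 at a preset correlation of 0.1. HK2 (-1.24 ± 0.30), lactate dehydrogenase A gene LDHA (-1.22 ± 0.07) and the glucose transporter SLC2A3 (-0.90 ± 0.19) fell, and ALDOC (0.69 ± 0.17) rose, in the authors' deposited table. LDHA and HK2 lie in lowered stretches of chromosomes 11 and 2. Of 24 tested hypoxia genes, 7 were lower and 2 higher in the authors' deposited table, with a median of -0.19. The hypoxia list passed (adjusted p = 0.0206), but not at a preset correlation of 0.05 (adjusted p = 0.118) or in rank form (adjusted p = 0.115). Carbonic anhydrase CA9 (-3.00 ± 0.20), VEGFA (-1.45 ± 0.11) and NDRG1 (-1.12 ± 0.08) fell, and BNIP3 (0.69 ± 0.12) and ERO1A (0.38 ± 0.14) rose, in the authors' deposited table.

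Of 20 tested genes of the unfolded protein response, 10 were lower and 2 higher in the authors' deposited table, 11 and 2 when adjusted over the list alone, with a median of -0.35 and a list adjusted p of 0.00135. The list adjusted p was 0.0741 at a preset correlation of 0.1, and 0.289 without genes in shifted chromosome stretches. EDEM1 (-1.46 ± 0.21), SYVN1 (-1.20 ± 0.12) and the disulfide isomerase PDIA6 (-1.10 ± 0.07) fell, and CRELD1 (0.74 ± 0.19) and HERPUD1 (0.47 ± 0.19) rose, in the authors' deposited table. Of 28 tested ATF4 and amino acid response genes, 7 were higher and 6 lower in the authors' deposited table, 8 and 6 when adjusted over the list alone. That list did not pass (adjusted p = 0.374), and its median of 0.03 and the direction of its test differed in sign. NUPR1 (3.22 ± 0.89), ATF3 (3.09 ± 0.43) and CTH (1.44 ± 0.35) rose, and the serine synthesis enzyme PHGDH (-1.63 ± 0.09), CEBPB (-1.28 ± 0.07) and ATF4 itself (-0.67 ± 0.09) fell, in the authors' deposited table. Of 23 tested cholesterol synthesis genes, 6 were higher and 4 lower in the authors' deposited table (list adjusted p = 0.655). MSMO1 (0.50 ± 0.13), EBP (0.42 ± 0.09) and MVD (0.40 ± 0.13) rose in the authors' deposited table.

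Of 23 tested p53 targets, 5 were higher and 3 lower in the authors' deposited table (list adjusted p = 0.374, with a median of -0.17 against a test direction above 0). CDKN1A, the BH3-only gene BBC3 (1.65 ± 0.21) and TP53I3 (1.61 ± 0.13) rose, and SESN1 (-1.01 ± 0.37), PHLDA3 (-0.77 ± 0.11) and TNFRSF10B (-0.46 ± 0.17) fell, in the authors' deposited table. Of 18 tested BCL2 family and apoptosis genes, 5 were higher and 2 lower in the authors' deposited table (list adjusted p = 0.374). The BH3-only genes BMF (2.23 ± 0.36), BBC3 and PMAIP1 (1.23 ± 0.17), which promote apoptosis, rose, and BCL2L1 (-0.80 ± 0.12), which opposes it, fell, in the authors' deposited table. BIRC5 (-0.25 ± 0.10) was also called lower in the authors' deposited table, a call lost after centring (adjusted p = 0.0803). Of 17 tested stemness and drug tolerance genes, 5 were higher and 6 lower in the authors' deposited table (list adjusted p = 0.552, with a median of -0.09 and a mean of 0.07). CD24 (2.14 ± 0.10), SOX4 (0.92 ± 0.21) and DKK1 (0.40 ± 0.11) rose, and the Notch pathway genes JAG1 (-1.41 ± 0.17), HES1 (-1.27 ± 0.09) and NOTCH3 (-1.26 ± 0.09) fell, in the authors' deposited table.

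**Figure D3:**
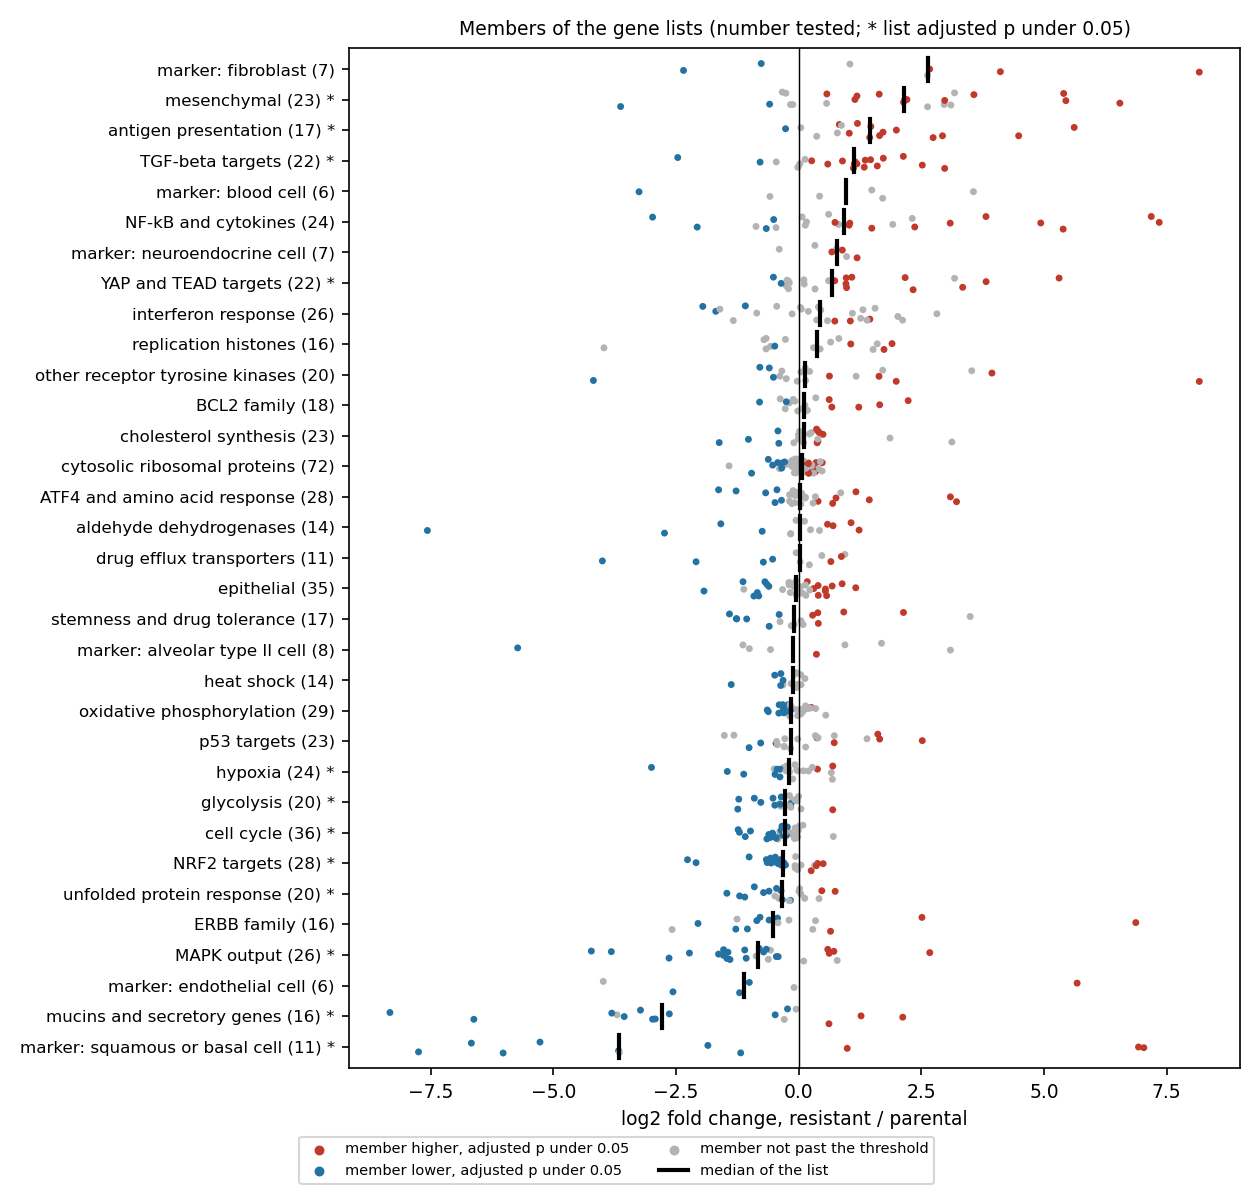
Each row is 1 of 33 gene lists fixed in advance, each point the log2 fold change (resistant over parental) of a tested member, and the black bar the list median. The 12 lists that passed an adjusted p of 0.05 carry an asterisk, from mesenchymal genes (median 2.14) to squamous or basal cell genes (median -3.66).

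The marker lists of fibroblasts, endothelium, neuroendocrine, alveolar and blood cells did not pass their tests. Of 7 tested fibroblast markers, 3 were higher and 2 lower in the authors' deposited table (list adjusted p = 0.743, with a median of 2.63, or 1.35 with 1 low member set to a count of 1). PDGFRB, COL1A1 (4.11 ± 0.82) and C1S (2.67 ± 0.42) rose, and FBLN1 (-2.35 ± 0.13) and SFRP1 (-0.76 ± 0.12) fell, in the authors' deposited table. Of 6 tested endothelial markers, 1 was higher and 3 lower in the authors' deposited table, 1 and 4 when adjusted over the list alone (list adjusted p = 0.118). ENG (-2.56 ± 0.27), CDH5 (-1.20 ± 0.38) and ESAM (-1.01 ± 0.14) fell, and ROBO4 was called higher at a mean count of 5.58, in the authors' deposited table. Of 7 tested neuroendocrine markers, 3 were higher and 0 lower in the authors' deposited table (list adjusted p = 0.118), namely NCAM1 (1.19 ± 0.37), DLL3 (0.89 ± 0.31) and UCHL1 (0.68 ± 0.06). Of 8 tested alveolar markers, 1 was higher and 1 lower in the authors' deposited table (list adjusted p = 0.988), namely CAV1 (0.36 ± 0.07) and HOPX, which was called lower at a mean count of 4.22. Of 6 tested blood cell markers, 0 were higher and 1 lower in the authors' deposited table, 1 and 1 when adjusted over the list alone (list adjusted p = 0.864), and the lower one was LYZ at a mean count of 4.43. At an unadjusted p of 0.05 of the authors' Wald test, 0 neuroendocrine markers were lower and 1 blood cell marker was higher.

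Fold changes also followed chromosomal position. Over 30 neighbouring genes the running median of the authors' deposited table reached -1.09 at the start of chromosome 2, against at most 0.509 in either direction over 1000 shuffled gene orders. Of 12 stretches that passed the 95th percentile of the shuffles, which was 0.43, 11 were lower and 1 higher in resistant cells. Not all went beyond the highest shuffle: those on chromosomes 3 and 5 reached only -0.497 and -0.486. On chromosome 11, the stretches from 47.4 to 65.9 Mb and from 67.6 to 73.6 Mb reached only -0.461 and -0.466. That of chromosome 22 from 41.2 to 50.3 Mb reached only -0.459. The 79 genes from 0.218 to 32.8 Mb of chromosome 2 had a median of -0.84 in the authors' deposited table, and the 83 genes from 27.2 to 61.9 Mb one of 0.49. Neighbouring stretches overlap because the windows do, so their ends are approximate. The other lowered stretches lie on chromosomes 2, 3, 5, 11 and 22, with medians from -0.59 to -0.09 in the authors' deposited table. Of tested genes with a position, lowered stretches held 9.89%. They held 26.6% of the 1911 positioned lower calls and 3.88% of the 1725 positioned higher calls of the authors' deposited table. The stretches were drawn from the same folds, so this split follows from their choice and is no separate evidence. Besides those mentioned above, SPRY4, HBEGF, LTBP3, PDIA6, SYVN1, ALDH1L1, ALDH3B2, FBLN1 and ESAM, which were lower, and TP53I3, TRIM29, ALDH3B1, NCAM1 and ROBO4, which were higher, lie in shifted stretches. Without the genes of all 12 stretches, 3087 genes passed, 1643 higher and 1444 lower.

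**Figure D4:**
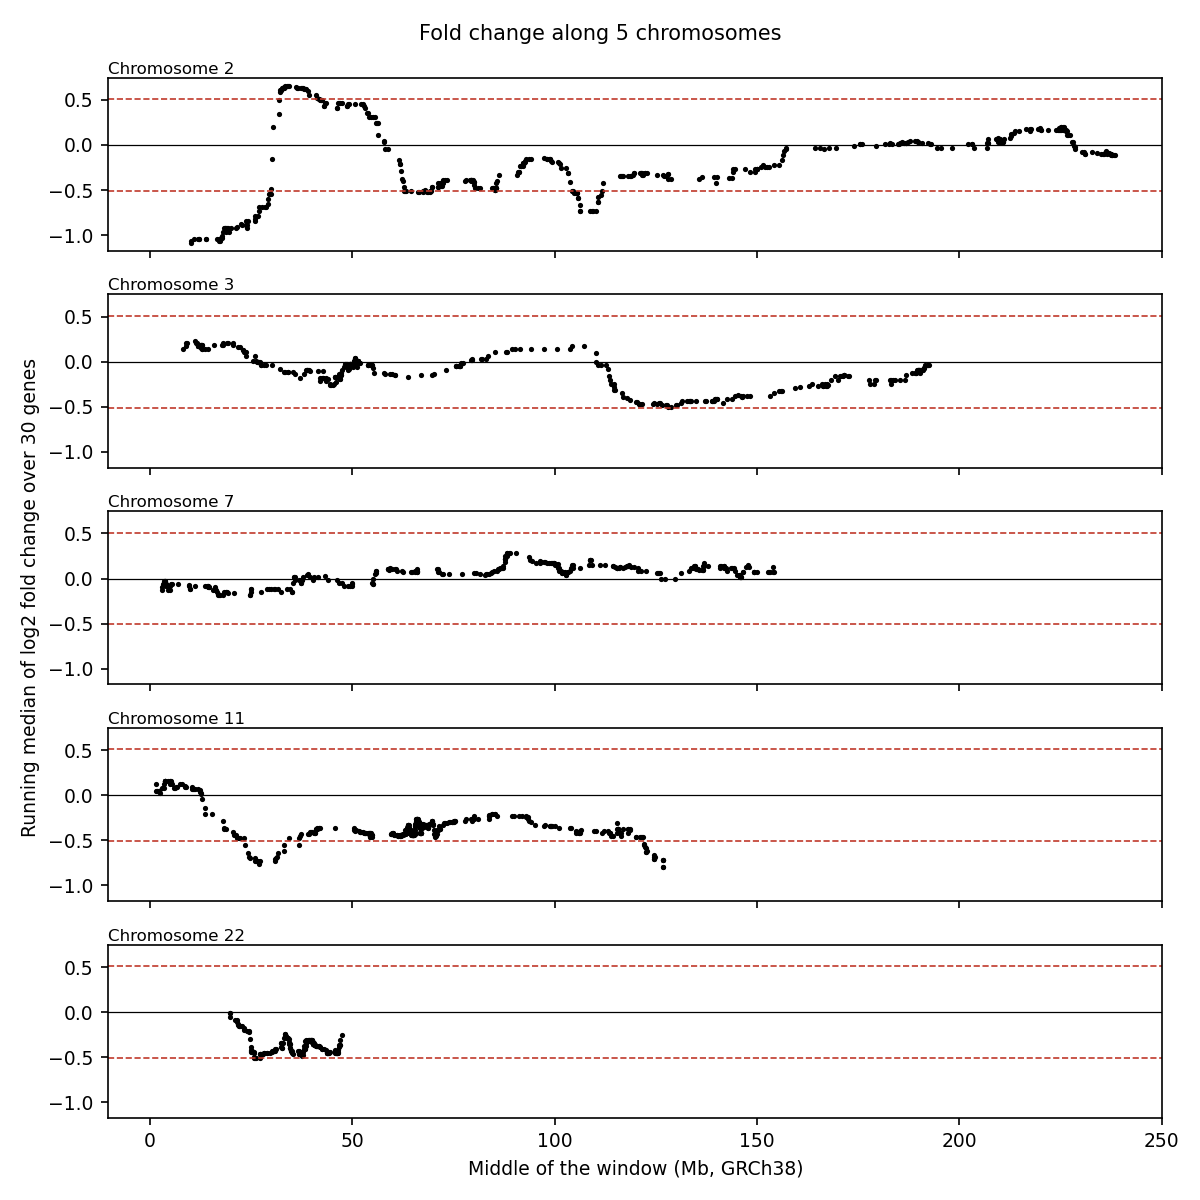
Each point is the median log2 fold change (resistant over parental) of 30 neighbouring genes with a mean normalized count of 50 or more, at the middle of the window in Mb, for chromosomes 2, 3, 7, 11 and 22. The dashed lines mark the highest value of 1000 shuffled gene orders (0.509), beyond which chromosome 2 fell to -1.09, while chromosome 7, which carries EGFR, stayed within the lines.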

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

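The alternatives with a filter on mean CPM, centring, scaling, a test against a 2-fold change, other preset correlations, the rank form and the removal of shifted stretches were chosen after seeing the data. Requiring an absolute log2 fold change of 1 gave 1382 genes, 731 higher and 651 lower, and testing against a 2-fold change gave 454, 220 and 234, since both ask for larger effects. Other settings gave 2871 to 3794 genes: 3682 without a low-count filter, 2871 at an adjusted p under 0.01, 3470 at a mean CPM of 5 or more, 3794 after centring, 3784 after scaling to equal sums and 3087 without shifted stretches. Of the genes that the naming rule takes or that were added, 2 lost their call after centring and after scaling, and 19 at an adjusted p under 0.01. Requiring an absolute log2 fold change of 1 removed the call of 58 of these genes, and testing against a 2-fold change that of 102. Of the 12 lists that passed, 7 did at a preset correlation of 0.1, 11 at 0.05, and 11 without shifted stretches, where only 31 lists could be tested; the rank form also gave 11, with NF-kB targets in and hypoxia and squamous genes out. The cause of the change at 0.1 lies in the larger variance that setting assumes. No called result turned its direction in these settings.

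No paired analysis was possible because the comparison table carries no replicate numbers. Other size factors, DESeq2 and limma-voom fits, a count minimum in at least 3 samples, leaving out each replicate, other splits of the samples, an estimated correlation and fry were not run, for want of values per library here. Whether 1 library decides a result is therefore open, and 1 library on the side read as parental had a size factor of 0.539 against 1.03 to 1.37 for the others. Genes with a mean count under 50 had a median standard error of 0.62, against 0.15 at 50 or more. At the standard errors of the table, 20.9% of simulated 1.5-fold changes were called, a share that was not computed at other depths.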

Other observations

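Of 72 tested cytosolic ribosomal protein genes, 14 were higher and 7 lower in the authors' deposited table, 16 and 7 when adjusted over the list alone, with a median of 0.06 and a list adjusted p of 0.513. After centring, 22 were higher and 6 lower. RPL12 (0.48 ± 0.06), RPL13A (0.35 ± 0.07) and RPL22 (0.34 ± 0.12) rose, and RPS7 (-0.96 ± 0.05), RPS23 (-0.62 ± 0.19) and RPL31 (-0.53 ± 0.06) fell, in the authors' deposited table, with RPS7 and RPL31 in lowered stretches of chromosome 2. Of 29 tested oxidative phosphorylation genes, 11 were lower and 1 higher in the authors' deposited table, 12 and 1 when adjusted over the list alone, and the list did not pass (adjusted p = 0.118). NDUFS3 (-0.64 ± 0.08), NDUFA2 (-0.62 ± 0.08) and ATP5G1 (-0.41 ± 0.07) fell and COX4I1 (0.25 ± 0.06) rose in the authors' deposited table. NDUFS3 and NDUFA2 lie in lowered stretches of chromosomes 11 and 5, the latter with a median fold change of only -0.09.

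Of 14 tested heat shock genes, 5 were lower and 0 higher in the authors' deposited table, as at an unadjusted p of 0.05 of the authors' Wald test, and the list did not pass (adjusted p = 0.197). HSPA4L (-1.38 ± 0.47), BAG3 (-0.49 ± 0.12) and the constitutive chaperone HSPA8 (-0.37 ± 0.06) fell in the authors' deposited table, HSPA8 in a lowered stretch of chromosome 11. Of 16 tested replication histone genes, 3 were higher and 1 lower in the authors' deposited table (list adjusted p = 0.167). Because primers started at the poly(A) tail, these counts cover only polyadenylated forms of the histone transcripts. The higher ones in the authors' deposited table were HIST1H2BK (1.90 ± 0.10), HIST1H2BD (1.74 ± 0.28) and HIST1H1C (1.06 ± 0.15), and the lower one was HIST1H4C (-0.49 ± 0.07).

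Of the tests that follow, the one on ribosomal protein genes was chosen only after the result was seen. Runs of neighbouring genes shifted together, with a largest absolute running median over 30 genes of 1.09 against 0.509 in the highest of 1000 shuffled orders (permutation p = 0.001, the smallest they can give), and windows of 15 and 60 genes gave 1.22 and 1.03 against 0.804 and 0.331 in the highest of 200 shuffled orders each. Gains and losses of chromosome segments between the cultures are a candidate explanation. Coordinated regulation of the genes that lie there stays open: the 5 ribosomal protein genes in lowered stretches had a median that differed by -0.51 from that of the 61 elsewhere, but the stretches had been drawn from the same folds, and RPS27A (0.44 ± 0.21, adjusted p = 0.116), where a lowered and the raised stretch overlap, was left out. For the fall of EGFR, loss of its segment is argued against by its 9 neighbours within 2 Mb, whose median was -0.054 (bootstrap SE 0.18), although MRPS17 (-0.998) and CCT6A (-0.47) were lower in the authors' deposited table, and a loss confined to EGFR was not tested. Whether the segments mark a clone selected by the drug or one that drifted in culture was not tested.

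The fibroblast markers PDGFRB, COL1A1 and C1S were higher in resistant cells, and fibroblasts mixed into the resistant cultures are a technical explanation, although FBLN1 (-2.35) and SFRP1 (-0.76) of the same list fell, from fitted parental counts of 471 and 370 in the authors' deposited table. Such cells would bring their most abundant transcripts, and the median mean normalized count of COL1A1, COL1A2, COL3A1, DCN and LUM was 0 in the authors' deposited table, under the bound set for it in advance. That bound was wrong, because genes that nearly all cells use, such as RPL10 at 0.571, also stand near 0 in the authors' deposited table, so that a 0 can mark a gene the assay or its counting missed. Of these 5 genes only COL1A1 had an adjusted p, at a mean count of 13.9 against 327 for PDGFRB in the authors' deposited table, and 1 gene does not exclude fibroblasts. Fibroblasts and a difference of the resistant cells themselves therefore cannot be told apart here, and other PDGFRB-positive cell types were not tested.

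HLA-B rose more than HLA-C, and reads reassigned between near-identical class I genes could give such a change. Reads moved from HLA-C would need a fall of that gene, but its log2 fold change was 1.03 in the authors' deposited table, so an exchange of reads with HLA-C is argued against, and exchange with other class I genes stays open here. A mismatch between the HLA alleles of the line and the reference would act on both groups and was not tested. Higher transcription of the class I genes in resistant cells remains an untested hypothesis, beside the higher NLRC5 (2.74 ± 0.40) in the authors' deposited table.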
